A study of Arabidopsis thaliana with 81 samples.

How the data were processed

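The 81 libraries were made from Arabidopsis thaliana seedlings, 57 for 3′ messenger RNA sequencing and 24 for chromatin immunoprecipitation (ChIP) with an anti-FLAG affinity gel. Per the labels' protocols, RNA libraries came from a kit that sequences the 3′ end of polyadenylated transcripts, so a gene's count does not scale with its length. For each RNA library the authors deposited whole-number counts of reads per gene beside a CPM value, which is the count over the total of all counted reads with the usual CPM scaling. The largest difference between the deposited CPM and the share computed from the counts was 0.0. Per the submitters' processing notes the tools were STAR for RNA, Trimmomatic, Bowtie2, Picard, deepTools and MACS2 for ChIP, and the build TAIR10, while their versions and the read-counting settings are not given in the sources used here. Each count table held 32833 gene identifiers, of which 32548 were paired with a symbol through a name table of assembly TAIR10.1, used for names only. Whether counting used the strand is not stated, so reads of overlapping or antisense genes, and reads shared by close paralogues such as CBF1 to CBF3 or COR6.6 and KIN1, may not be told apart.

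For each ChIP library the authors deposited a list of peaks with a score, a fold enrichment, a −log10 p-value, a −log10 q-value and a summit position. Peaks were called separately in each library, and the lists reach down to a −log10 p of 1.0, so they include weak peaks. No untagged control library was used here. Fold and q of a peak are the authors' values and were used only to describe, rank or filter peaks within a list. No reference genome was used, so a search for CAMTA motifs and a test of cold-responsive genes near peaks were not run, and peaks at the promoters of named genes were not located.

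The labels give genotype, temperature and, for most RNA libraries, time. They describe every library as single, and nothing says that libraries with the same labels came from separate cultures. P-values therefore measure the spread between these libraries, which may be technical or may come from a treatment that the labels leave out. Libraries fall into library sets named by the leading number of their titles, 190 and 191. Total counts ranged from 7578592 to 16000647 in the 28 libraries of set 190, and from 10803826 to 21075393 in the 29 of set 191. Organelle-encoded genes took 1.301% to 10.752% of the reads. No pair of libraries had identical counts, and the chi-square statistic per degree of freedom between same-labelled libraries at 22 °C ranged from 27.64 to 595.19, far above sampling noise, so each library was counted as 1 sample.

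Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, robust dispersion), with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error (SE) is the absolute log2 fold change divided by the square root of F. The cold effect was 4 °C minus 22 °C over 28 libraries of the wild type line COL with time as a factor, over 19 libraries of 7 genotypes at 2 h with genotype as a factor, and over 9 libraries of 3 FLAG-tagged lines, whose time the labels do not give, with line as a factor. Genotypes were compared in the 19-library fit with temperature as a covariate, and the difference in cold effect between genotypes with an interaction term. Only 1 library per genotype is labelled 4 °C, so its spread is assumed to equal that of the other groups. Comparing los1-1 with C24 and ice1-1 with pCBF3LUC follows background knowledge of these mutants. For 161 list genes an exact two-sided permutation of the temperature labels within times (18954 arrangements) was added, with Benjamini-Hochberg adjustment over those genes.

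Before the data were examined, 17 gene lists, the tests, most of the other settings and the rule for named genes were fixed. The rule always names the targeted genes and CBF1 to CBF3. It adds from each list up to 4 members with the smallest adjusted p, and the 10 largest rises and 10 largest falls per cold comparison (5 for a genotype contrast) among genes past the threshold. Those genes also needed an average log2 CPM of at least 3 and, for cold, the same sign in every time, genotype or line. Other genes named from counts of 5 or fewer, and the remaining genes of the early against late comparison, were chosen after their values were seen. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, beside an estimated correlation and fry. ChIP summits were extended by 150 bp and merged into 85786 regions, and the presence of a peak was compared with a two-sided Fisher exact test and, as an alternative added later, with an exact test that keeps the R number of the peak names as a block. Alternatives were DESeq2 1.42.0 with a Wald test and its size factors, limma voom with sample weights, no filter on low counts, left-out libraries, summed counts and, added after the data were seen, 1 surrogate variable from sva 3.50.0. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the rest.

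The fits were tested on simulated counts with 200 changed genes. In the COL cold comparison the fit recovered 53.7%, 80.6% and 98.5% of genes changed by a log2 of 1, 2 and 4, with 3 false calls. In the 7-genotype cold comparison it recovered 34.3%, 70.1% and 89.4%, and in the FLAG lines 0%, 23.9% and 75.8%. For camta123 against COL the shares were 0%, 17.9% and 68.2%, for CYHr1 against COL 1.5%, 17.9% and 66.7%, for los1-1 against C24 3%, 34.3% and 75.8%, and for ice1-1 against pCBF3LUC 0%, 19.4% and 69.7%. The early against late comparison recovered 1.5%, 31.3% and 78.8%. The interactions recovered 0% even at a log2 of 4. These shares and false calls hold for the simulated counts only. When the real libraries were regrouped, 3 (COL), 5 (7 genotypes) and 2 (FLAG lines) of the other splits gave any call. The median was 0 in each, but the highest counts were 573, 5247 and 4961. The simulation therefore does not give the number of false calls to expect in the real libraries. The ChIP test recovered 100.0% of regions present in all CAMTA libraries and no ICE1 library, and 28.0% of those present at 90% against 10%, with 0 false calls among 85786 regions. With the R number as a block these were 100.0% and 4.0%, also with 0 false calls. The 200 changed regions were planted together, so many could reach the smallest possible p at once. In the real lists only 3 regions reached that of the Fisher test, and none passed after adjustment. The ChIP shares therefore do not hold for the real lists.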

Results

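The series measured messenger RNA and FLAG-tagged protein binding in Arabidopsis seedlings held at 22 °C or moved to 4 °C. Its title names the ribosome as a sensor of cold, and its genotypes carry changes in the translation machinery (los1-1, in translation elongation factor LOS1) or in transcription factors tied to cold gene expression (ice1-1 and camta123). CYHr1 is named as the labels give it. The RNA time course in the wild type line COL covered 0.25, 0.5, 1, 2, 4 and 6 h, with 7 libraries at 4 °C and 21 at 22 °C. A second set covered 7 genotypes at 2 h with 7 libraries at 4 °C and 12 at 22 °C. Lines CAMTA2-FLAG, CAMTA3-FLAG and FLAG-ICE1 added 3 libraries at 4 °C and 6 at 22 °C, and 1 further COL library at 6 h belonged to the second set. Total counts per RNA library ran from 7578592 to 21075393. Most libraries labelled alike at 22 °C differed strongly from each other, and this spread is part of the error of every RNA test. The COL pairs at 0.25 and 0.5 h differed less, with 38 and 51 of 9434 genes at least 4-fold apart. In the other pairs these numbered 596 to 3779.

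In the COL time course, cold raised CBF3, a transcription factor that activates cold-regulated genes, and effector genes downstream of the CBF family. The log2 fold change of CBF3 was 3.32 ± 0.85 (SE, 7 against 21 libraries, edgeR adjusted p = 0.0123), and the 4 °C level lay above all same-time 22 °C libraries at 5 of 6 times. CBF3 was 3.78 CPM at 0.25 h, 12.9 at 0.5 h, 50.01 at 1 h, 79.1 and 281 in the 2 h libraries, 73.9 at 4 h and 63.7 at 6 h. At 22 °C it ranged from 0.125 to 95.9 CPM. The exact permutation p for CBF3 was 0.00127 (0.0255 adjusted over the listed genes). That test passed for 20 of 161 listed genes, and for 15 of the 43 listed genes that edgeR called. CBF1 (log2 2.25 ± 1.06, adjusted p = 0.124) and CBF2 (1.02 ± 0.97, adjusted p = 0.458) did not pass, and CBF2 reached 1173 CPM in a library labelled 22 °C. Both passed with 1 surrogate variable (log2 4.57 and 3.37) and with voom (4.01 and 2.36), and CBF1 with DESeq2 (2.33).

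The other large rises in COL included UGT78D3, a flavonol glycosyltransferase (log2 4.75 ± 0.64, edgeR adjusted p = 8.23e-05), and MYB111, a regulator of flavonol synthesis (3.21 ± 0.46). UGT78D3 was higher than every same-time 22 °C library at 6 of 6 times, and MYB111 at 5. AT1G08347 rose by 3.49 ± 0.24, AT4G18422 by 3.39 ± 0.56, the bHLH factor AIF1 by 2.86 ± 0.55 and the chloroplast envelope protein OEP6 by 2.79 ± 0.33, each above all 22 °C libraries at 6 of 6 times. FRO2, a root ferric chelate reductase, rose by 2.70 ± 0.44 (5 of 6 times), and AT4G18650 by 3.49 ± 0.70 (4 of 6). The largest falls had wide errors. On the log2 scale these were −5.30 ± 1.79 for AT3G12910, −4.81 ± 1.68 for the ethylene synthesis gene ACS8, −4.66 ± 1.53 for the salicylic acid synthesis gene PBS3, −4.56 ± 1.38 for NAC036 and −4.53 ± 1.19 for AT5G41740. NAC036 and AT5G41740 lay below all 22 °C libraries at 5 of 6 times, ACS8 and PBS3 at 4, and AT3G12910 at only 1. The remaining named falls were AT1G20520, AT2G20150, AT4G02170, AT5G52760 and AT4G37290.

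**Figure D1:**
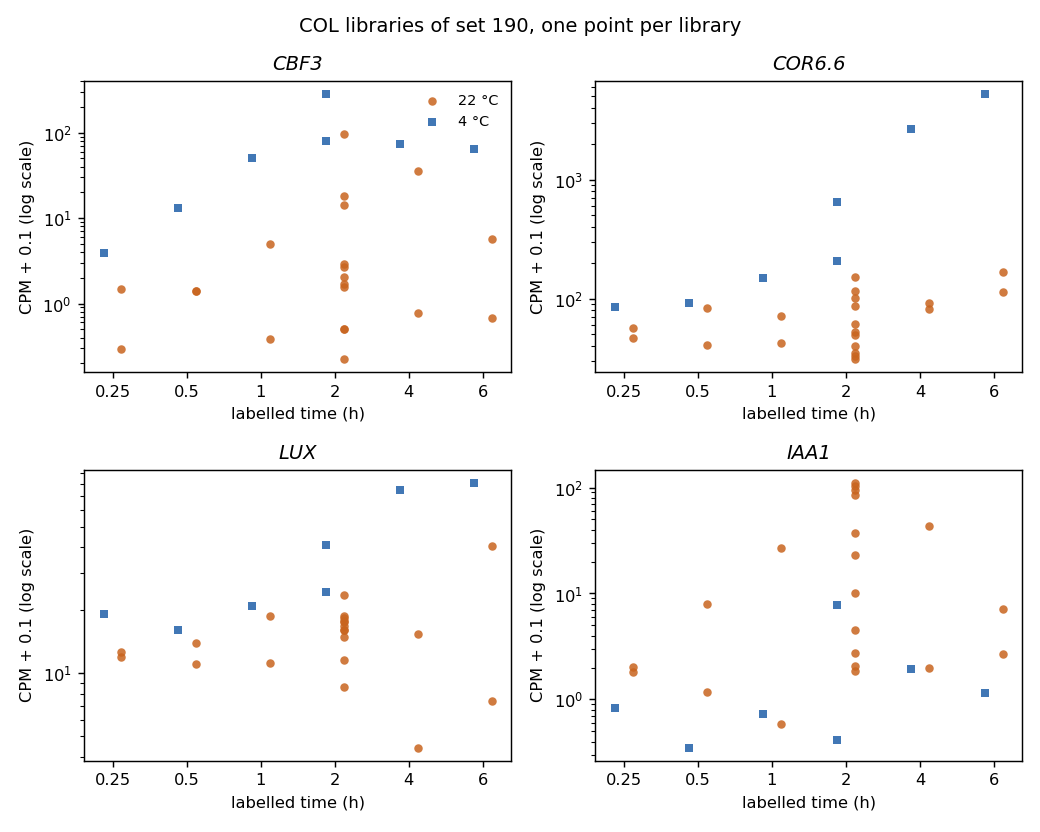
CPM (log scale, 0.1 added) of CBF3, COR6.6, LUX and IAA1 against labelled time (evenly spaced) in the COL libraries of set 190, with 1 point per library and colour for temperature. CBF3 at 4 °C lies above all same-time 22 °C libraries at 5 of 6 times and COR6.6 at 6 of 6, while IAA1 at 22 °C spreads from 0.480 to 110 CPM.

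Of 16 measured COR genes, which encode cold-induced protective proteins, 7 rose and 0 fell in COL (12 up and 1 down adjusted over the list alone). Only 3 of 18 rose with 1 surrogate variable (8 over the list alone). COR6.6 rose by log2 2.66 ± 0.44, above all 22 °C libraries at 6 of 6 times, with an exact permutation p of 5.28e-05, the smallest possible. The dehydrin LTI30 rose by 3.23 ± 0.74 (4 of 6 times), COR15B by 3.93 ± 0.98 (3 of 6) and COR78 by 3.26 ± 0.74 (2 of 6, and below all at 2). The exact permutation passed for 5 of 18 COR genes, LTI30 (adjusted p = 0.0156) among them, but not for COR15B or COR78 (adjusted p = 0.078 each). Camera gave the COR list an adjusted p of 0.000109, but the adjusted p = 0.645 with an estimated correlation. Of 14 clock genes 3 rose and 0 fell, with the same 3 adjusted over the list alone: ELF4 (2.38 ± 0.38), LUX (1.14 ± 0.24) and PRR5 (2.86 ± 0.49), though PRR5 lay above all 22 °C libraries at 3 of 6 times and below all at 1. ELF4 and LUX encode evening complex proteins. The clock list had a camera adjusted p of 0.0377 (adjusted p = 0.645 with an estimated correlation). Of 5 measured genes of the CBF list, CBF3 alone passed, also over the list alone (camera adjusted p = 0.0732). In the fit with 1 surrogate variable 4 of the 5 rose, also over the list alone (camera adjusted p = 3.34e-05, and adjusted p = 0.176 with an estimated correlation).

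Cytosolic ribosomal protein genes were higher in cold COL seedlings, with 9 of 15 up and 0 down (12 up adjusted over the list alone). RPL5A rose by log2 0.77 ± 0.19, RPL23AA by 0.91 ± 0.27, RPS13A by 0.68 ± 0.20 and RPL27AC by 0.72 ± 0.22. Of the 9 only RPL5A passed the exact permutation (adjusted p = 0.0302), which gave 0.0571 for RPL23AA and RPS13A and 0.0572 for RPL27AC. Camera gave an adjusted p of 4.29e-05 (adjusted p = 0.645 with an estimated correlation). With a surrogate variable 7 of the 15 rose (9 over the list alone), and the list's median log2 was 0.33 against 0.555. RPL5A spanned 64.1 to 445 CPM among the 22 °C libraries and 355 to 463 CPM at 4 °C. Elongation factor gene eEF1A4 was the 1 of 5 elongation genes to pass (0.73 ± 0.21), and LOS1 did not (0.31 ± 0.18, adjusted p = 0.211). Of 7 ribosome biogenesis genes only the nucleolin gene NUC2 passed, at −1.30 ± 0.37. The exact permutation passed for eEF1A4 (adjusted p = 0.0371) and not for NUC2 (0.114) or the photosynthesis gene RBCS1B (0.0571). Photosynthesis genes passed by edgeR in 1 of 12 (RBCS1B, 0.81 ± 0.25), ER chaperones in 0 of 6 and heat shock proteins in 0 of 8 (camera adjusted p = 0.0397, and adjusted p = 0.645 with an estimated correlation). Each of these counts, other than that of ribosomal proteins, was unchanged when adjusted over the list alone. The exact permutation called 3 heat shock genes lower, HSFA2 and HSP90.1 (adjusted p = 0.032 each) and HSP70 (0.0368). With 1 surrogate variable 1 of 8 heat shock genes (3 over the list alone), 1 of 6 ER chaperones (2 over the list alone) and 3 of 12 photosynthesis genes fell.

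Hormone and defence genes in COL moved both ways. Of 8 primary auxin response genes 2 fell, IAA1 (−3.48 ± 1.09) and IAA29 (−3.28 ± 1.16), and 8 fell when adjusted over the list alone (camera adjusted p = 0.0229, and adjusted p = 0.645 with an estimated correlation). IAA1 at 22 °C spanned 0.480 to 110 CPM, and IAA29 lay below all 22 °C libraries at 3 of 6 times and above all at 1. Of 10 salicylic acid and immunity genes, the pathogenesis-related gene PR5 rose by 2.07 ± 0.45 at 6 of 6 times, while PBS3, FMO1 and CBP60G fell (7 down adjusted over the list alone). Of 15 early cold transcription factors CRF3 (1.03 ± 0.28) and HSFC1 (1.31 ± 0.38) rose and 3 fell, among them WRKY40 (−3.51 ± 1.09) and WRKY33 (−2.89 ± 0.97), and 7 fell over the list alone. CRF3 lay above all 22 °C libraries at 3 of 6 times and below all at 2. None of these 8 auxin and 10 immunity genes fell with 1 surrogate variable (0 and 0, also over the list alone), and 1 early cold factor did. The median log2 of the auxin list then went from −3.292 to −0.629, that of the immunity list from −2.535 to −0.66 and that of the early cold factors from −1.959 to 0.127. Abscisic acid genes ABI2 (−1.65 ± 0.39) and RAB18 (−1.48 ± 0.46) fell among 10. Of 9 jasmonate genes LOX2 rose and AOC1 fell, and of 3 touch genes TCH3 fell by 2.82 ± 0.98 (3 down adjusted over the list alone). Root markers IRT1, an iron transporter (2.61 ± 0.56), and PYK10 (1.49 ± 0.41) rose among 8. In the fit with 1 surrogate variable 0 jasmonate genes passed, 2 of 3 touch genes fell and 2 root markers fell beside 2 that rose. List medians there were −0.973 against −2.795 for touch, −0.416 against −0.971 for jasmonate, 0.291 against −0.352 for abscisic acid and −0.052 against 0.134 for root markers. Among targeted genes CAMTA2 (−0.84 ± 0.22) and CAMTA3 (−1.85 ± 0.60) fell, while ICE1, SCRM2 and CAMTA1 were at 0.34 ± 0.17, 0.63 ± 0.23 and −0.25 ± 0.14 and did not pass, though SCRM2 did in 4 other settings. Of these genes PR5 (adjusted p = 0.0064), AOC1 (0.0068), IRT1 (0.0255), CAMTA2 (0.032), RAB18 (0.0368) and PYK10 (0.0368) also passed the exact permutation. It did not pass for IAA1 (0.0722), IAA29 (0.134), PBS3 (0.0607), FMO1 (0.114), CBP60G (0.0938), CRF3 (0.0607), HSFC1 (0.0635), WRKY40 (0.0813), WRKY33 (0.134), ABI2 (0.0571), LOX2 (0.0813), TCH3 (0.104) or CAMTA3 (0.102).

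In all, 1925 genes rose and 1856 fell among 19362 tested in COL, with 454 above and 193 below all 22 °C libraries at all 6 times where chance gives 1.02 each. Without the 2 h time point, which holds 13 of the 28 libraries, 38 genes passed and 3480 had an unadjusted p under 0.05. The split was 32 up and 6 down there, 2264 and 3352 with DESeq2, and 1400 and 2375 with counts summed per time and temperature, where 2599 of the 3781 genes were called again. AT1G08347 and OEP6 were the only ones of 51 named called genes that passed in every other setting. Leaving out single 4 °C libraries gave 2403 (1 h), 1537 and 2027 (the 2 h libraries), 1653 (4 h) and 1986 calls (6 h), and voom gave 7612. Rises then outnumbered falls by 1017 to 520 without library 1 at 2 h, 1122 to 531 without that at 4 h and 1250 to 736 without that at 6 h.

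Whether the cold effect changed over time was asked by comparing 2, 4 and 6 h with 0.25, 0.5 and 1 h. Same-labelled 22 °C pairs differed at least 4-fold in 38, 51 and 596 of 9434 genes at 0.25, 0.5 and 1 h. At 4 and 6 h these were 2346 and 3779, so the comparison cannot tell a changed cold effect from this spread. With 1 surrogate variable the median log2 difference went from −3.183 to −0.459 for auxin genes and from 1.278 to 1.496 for clock genes. The clock genes PRR5 (log2 difference 4.22 ± 0.79, edgeR adjusted p = 0.0443) and ELF4 (3.02 ± 0.56, adjusted p = 0.0424) rose more at the later times. So did AT5G59350 (3.49 ± 0.56), AT3G10910 (3.01 ± 0.49), AT1G07050 (4.20 ± 0.73) and AIRP2 (3.97 ± 0.69). AT2G43620 (−4.50 ± 0.85), AT2G31730 (−2.46 ± 0.44), GSTF10 (−2.41 ± 0.43), SUVR1 (−2.87 ± 0.43) and LSF2 (−1.69 ± 0.32) went the other way. These were all the 6 higher and 5 lower genes of 19814. Over the list alone 7 of 14 clock genes and 10 of 18 COR genes were higher late. The clock list kept an adjusted p = 0.022 with an estimated correlation, and the COR list had an adjusted p = 0.0573. These counts were 11 and 13 with 1 surrogate variable, where 4 of each list passed over all genes (adjusted p = 0.0392 for clock and 0.155 for COR genes with an estimated correlation). In that fit 6 of 6 ER chaperones were lower late over the list alone (adjusted p = 0.269 with an estimated correlation). CBF1, CBF2 and CBF3 gave −2.48 ± 2.17, −1.21 ± 2.01 and −0.01 ± 1.07 and did not pass, nor did any targeted gene, of which ICE1 (1.11 ± 0.28, adjusted p = 0.111) came nearest. ICE1 passed with voom (0.95), DESeq2 (1.08) and 1 surrogate variable (1.04), and without library 2 at 4 °C and 2 h (1.35). The count was unstable, at 530 with DESeq2 (365 higher and 165 lower late), 2556 with voom and 374 with 1 surrogate variable. Without single 4 °C libraries it was 0 (0.25 h), 1 (0.5 h), 0 (1 h), 268 (library 2 at 2 h), 1 (4 h) and 5 (6 h). Without single 22 °C libraries it was 3 (each at 0.25 and 0.5 h), 6, 6, 35 and 96 (libraries 4, 5, 6 and 11 at 2 h) and 7 (library 1 at 4 h).

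Across the 7 genotypes at 2 h, cold raised CBF3 in every genotype. The log2 fold change was 5.37 ± 0.95 (7 against 12 libraries, edgeR adjusted p = 0.00329), with 15.3 to 123 CPM at 4 °C and 0.0596 to 10.7 CPM at 22 °C. CBF3 at 4 °C was 90.7 CPM in COL, 68.4 in camta123, 57.7 in CYHr1, 100 in C24, 123 in los1-1, 24.3 in pCBF3LUC and 15.3 in ice1-1. CBF1 (2.84 ± 1.26, adjusted p = 0.130) and CBF2 (1.61 ± 1.59, adjusted p = 0.496) did not pass. Both passed with 1 surrogate variable (5.375 and 4.505), and CBF1 with voom (3.20). Other rises were AT4G18422 (6.55 ± 0.65), AT1G11210 (5.23 ± 0.44), MAPKKK17 (3.78 ± 0.62), AT5G17460 (3.28 ± 0.31) and MYB111 (3.27 ± 0.35), each higher in 7 of 7 genotypes, and the glucose 6-phosphate transporter gene GPT2 (3.56 ± 0.89, 6 of 7). Falls in 7 of 7 genotypes were MAKR6 (−5.15 ± 1.31) and AT2G08950 (−4.40 ± 0.63). ACS11, a second ethylene synthesis gene, AT1G53620 and AT1G56150 lay below all 22 °C libraries in 6, PEPC1, ZAT7 and CNGC19 in 5, and AT1G76210, which fell by 7.01 ± 2.23, in 4.

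**Figure D2:**
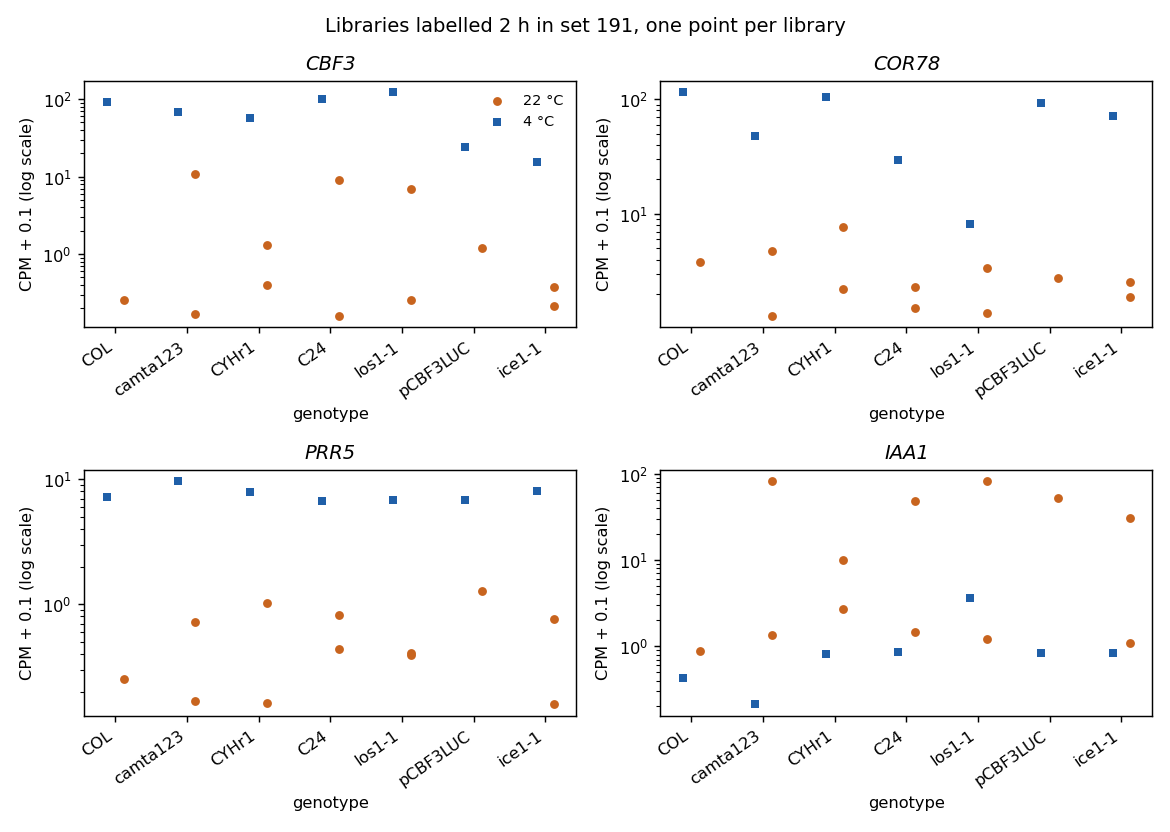
CPM (log scale, 0.1 added) of CBF3, COR78, PRR5 and IAA1 in the 19 libraries labelled 2 h of set 191, by genotype, with 1 point per library and colour for temperature. CBF3, COR78 and PRR5 at 4 °C lie above the 22 °C libraries in 7 of 7 genotypes, and IAA1 lies below them in 6 of 7.

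COR genes rose across the 7 genotypes, with 12 of 17 up and 0 down, and the same 12 adjusted over the list alone. COR15B rose by log2 6.46 ± 0.39, COR78 by 4.27 ± 0.42, KIN1 by 3.68 ± 0.35 and COR6.6 by 3.22 ± 0.27, each in 7 of 7 genotypes, as did LTI30 (4.28 ± 0.45) and ERD10 (2.62 ± 0.25). The COR list passed camera (adjusted p = 3.47e-29) and kept an adjusted p = 0.00141 with an estimated correlation. Clock genes rose in 7 and fell in 1 of 14, led by PRR5 (4.13 ± 0.48), ELF4 (2.31 ± 0.40), ELF3 (1.35 ± 0.20) and LHY (1.28 ± 0.18), with a camera adjusted p of 2.8e-06 (adjusted p = 0.162 with an estimated correlation). The CBF list had 1 of 5 up (camera adjusted p = 0.00184, and adjusted p = 0.474 with an estimated correlation). It had 5 of 5 up with 1 surrogate variable, also over the list alone, at a median log2 of 4.75 against 2.08 (adjusted p = 0.00471 with an estimated correlation). Primary auxin genes fell in 5 of 8 (8 over the list alone), such as IAA5 (−6.15 ± 1.57) and IAA3 (−3.60 ± 1.00), with a camera adjusted p of 0.00344 (adjusted p = 0.665 with an estimated correlation). HSFA2 fell by 3.94 ± 1.02, the 1 of 7 heat shock genes to pass (6 over the list alone, camera adjusted p = 0.0132, and adjusted p = 0.665 with an estimated correlation). Ribosomal proteins passed in 0 of 15 (camera adjusted p = 0.0265, and adjusted p = 0.887 with an estimated correlation). As many as 10 of the 15 rose with 1 surrogate variable (11 over the list alone, adjusted p = 0.412 with an estimated correlation), at a median log2 of 0.31 against 0.30. PR5 rose by 1.96 ± 0.26 and ALD1 fell by 7.04 ± 1.97 among 11 immunity genes. CRF3, HSFC1, LOX2, RBCS1B and PYK10 rose and ABI2 fell, and 0 members passed among ER chaperones, ribosome biogenesis, touch and elongation genes. With 1 surrogate variable 3 of 3 touch genes, 6 of 7 heat shock genes, 4 immunity genes and 3 root markers fell. In that fit 4 of 5 elongation genes (5 over the list alone), 4 abscisic acid genes and 5 early cold factors rose, while 2 abscisic acid genes and 2 early cold factors fell. The list median moved from −0.798 to 0.632 for early cold factors, from −2.0 to −0.854 for immunity and from −2.251 to −1.064 for touch genes. Among targeted genes CBF3 alone passed, and CAMTA3 had −1.52 ± 0.74 (adjusted p = 0.162). CAMTA3 (−0.885) and LOS1 (0.25) passed with 1 surrogate variable, and with voom (−1.41 and 0.38).

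The 7-genotype fit called 1568 genes up and 1913 down of 20669, and 945 genes lay above and 870 below in all genotypes where chance gives 21.3. The count was 5544 with DESeq2, 8369 with voom and 7404 with 1 surrogate variable. It was 1447 without the 4 °C library of camta123, 1882 without that of CYHr1, 1903 without that of ice1-1, 2285 without that of C24, and 1825 and 1826 without the pCBF3LUC libraries at 4 and 22 °C. The COL time course and this set share no library. Of 3769 genes called in COL and tested in both, 99.1% had the same sign across the 7 genotypes (Pearson r 0.851 and Spearman rho 0.831 across genes, which are not independent replicates). In both, 905 genes rose and 867 fell, where independent lists give 154 and 179.7, and 0 were called in opposite directions. With 1 surrogate variable in each fit, r was 0.757 and rho 0.752, with 98.9% of 2531 genes at the same sign and 1 opposite. Same-labelled 22 °C libraries spread widely in both sets. This agreement alone therefore cannot tell cold from a factor that both sets of 22 °C libraries may share.

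The FLAG-tagged lines showed a cold rise of COR genes as well. COR15B rose by log2 4.25 ± 0.47, LTI30 by 3.12 ± 0.43, COR78 by 2.71 ± 0.22, COR6.6 by 1.81 ± 0.19 and COR413-PM1 by 1.61 ± 0.20 (3 against 6 libraries), the 5 of 18 COR genes that passed (8 over the list alone, camera adjusted p = 7.33e-13, and adjusted p = 0.210 with an estimated correlation). The count was 15 of 18 with 1 surrogate variable (16 over the list alone, adjusted p = 0.049 with an estimated correlation). AT1G24580 (3.55 ± 0.51), the glutathione transferase gene GSTU28 (3.47 ± 0.47), ABCI21 (3.10 ± 0.46), MYB13 (2.60 ± 0.33) and ASG4 (2.54 ± 0.39) also rose. The receptor kinase gene IOS1 (−3.03 ± 0.45), AT5G07580 (−2.86 ± 0.23), the nitrate efflux gene NAXT1 (−2.49 ± 0.31), the phosphate transporter gene PHT1;4 (−1.84 ± 0.24) and the sucrose transporter gene SUC1 (−1.81 ± 0.27) fell. CBF3 (2.57 ± 1.65, adjusted p = 0.394), CBF2 (0.80 ± 1.75) and CBF1 (−0.86 ± 1.92) did not pass, but CBF3 did with voom (5.22), and CBF3 (5.42) and CBF2 (4.48) with 1 surrogate variable. No member of the other lists passed over all genes without that variable. With it 13 of 14 clock genes, 5 of 10 abscisic acid genes, 4 of 12 photosynthesis genes, 4 of 15 early cold factors and 2 of 4 CBF genes rose. In the same fit 6 of 6 ER chaperones, 5 of 8 auxin genes, 4 of 10 immunity genes, 3 of 8 heat shock genes, 3 of 7 ribosome biogenesis genes and 2 of 3 touch genes fell, as did 2 abscisic acid genes and 3 early cold factors. List medians then moved from −3.942 to −1.172 for touch, −4.259 to −1.915 for immunity, −3.037 to −1.641 for auxin and −2.637 to 0.205 for early cold factors. Over the list alone 5 of 14 clock genes rose (camera adjusted p = 3e-08, and adjusted p = 0.478 with an estimated correlation) and 2 of 8 auxin genes fell (camera adjusted p = 0.0168, and adjusted p = 0.827). Of the tagged genes ICE1 stood apart in its own line, at 245 to 436 CPM in FLAG-ICE1 against 8.63 to 26.9 in the other lines. CAMTA2 was at 29.4 to 52.4 CPM in CAMTA2-FLAG, against 4.15 to 4.31 in CAMTA3-FLAG and an overlapping 17.1 to 35.01 in FLAG-ICE1. CAMTA3 was at 61.0 to 421 CPM in CAMTA3-FLAG, against 3.55 to 52.1 in CAMTA2-FLAG and an overlapping 12.6 to 83.2 in FLAG-ICE1. In all 114 genes rose and 39 fell of 19400, and 2765 lay above and 2640 below in every line where chance gives 719. Of 3628 genes called in COL and tested in these lines 85.0% had the same sign (Pearson r 0.741 and Spearman rho 0.585 across genes), with 53 up and 15 down in both where independent lists give 10.9 and 3.8. That agreement carries the same limit as the one with the 7 genotypes. The count was 68 without the second CAMTA2-FLAG library at 22 °C and 0 without any other single library, against 2579 with DESeq2, 3252 with voom and 5052 with 1 surrogate variable. The share of rises was lower in these fits, with 1220 up and 1359 down by DESeq2, 1915 and 1337 by voom and 2541 and 2511 with the surrogate variable.

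In camta123 the targeted gene CAMTA1 was at 1.00 to 2.06 CPM against 8.77 to 10.06 in COL (log2 −2.62 ± 0.31, 3 against 2 libraries, edgeR adjusted p = 0.00967). CAMTA2 was at 4.20 to 8.35 CPM against 13.4 to 15.8 (−1.20 ± 0.51, adjusted p = 1.0), and passed with 1 surrogate variable (−1.54). CAMTA3 was at 4.00, 75.5 and 4.999 CPM against 6.16 to 7.96 in COL (1.25 ± 1.37, adjusted p = 1.0), and a 3′ tag outside a disrupted part of a gene checks nothing. GUS2, which encodes a glucuronidase, was at 0.0667 to 0.167 CPM against 14.4 to 20.2 (−6.98 ± 0.61, adjusted p = 0.00043). These were the 2 genes called by edgeR, with 751 at an unadjusted p under 0.05 and 19 called by DESeq2 (6 higher and 13 lower). CBF1, CBF2 and CBF3 had −0.98 ± 2.12, 0.59 ± 2.84 and 1.82 ± 1.82 and did not pass, and CBF2 (−0.575) and CBF3 (−0.008) turned sign with 1 surrogate variable. That variable was 0.225 in the only COL library at 22 °C and 0.327 and −0.339 in those of camta123. CAMTA1 was the only member of the 17 lists that edgeR called without a surrogate variable. The count was 1 without either COL library and 4 without either pCBF3LUC library.

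In CYHr1 1 gene differed from COL. RIC5 was at 14.3 to 29.9 CPM and at 0 in both COL libraries, which is at least 266-fold higher against a floor of 3 counts over the summed COL reads (counting error only). It was lost without either COL library, and DESeq2 called 19 genes, 9 higher and 10 lower. CBF1, CBF2 and CBF3 had −0.38 ± 2.04, 0.02 ± 2.67 and −0.29 ± 1.67 (CBF2 −0.433 with 1 surrogate variable), and no list member passed. In los1-1 LOS1 itself was at 1036 to 1563 CPM against 619 to 1219 in C24 (0.43 ± 0.31, adjusted p = 0.953), and the count of a point mutant's transcript does not check its label. AT5G62720 (2.93 ± 0.35), AT3G62460 (3.22 ± 0.40) and AT4G26670 (1.54 ± 0.23) were higher in los1-1 and AT5G26622 (−3.18 ± 0.47) and AT5G19580 (−1.29 ± 0.19) lower. This count of 5 fell to between 0 and 3 without any single library, and was 111 with DESeq2 and 207 with voom (156 higher and 51 lower). CBF1, CBF2 and CBF3 had 1.16 ± 1.87, −0.63 ± 2.37 and −0.35 ± 1.45 (CBF2 0.624 and CBF3 0.452 with 1 surrogate variable), and no list member passed. The labels give the C24 libraries the cultivar Col-0, so the background of this comparison is not settled by them. A surrogate variable added to the fit gave 1 of 10 abscisic acid genes lower and 1 of 5 elongation genes higher.

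The ice1-1 libraries held transcripts of seed storage genes and, beside them, of AT1G47540, which is not counted here as a storage gene. AT1G47540 (157 to 253 CPM), the seed albumin genes SESA3 (146 to 203 CPM), SESA5 (52.2 to 104 CPM) and SESA2 (65.3 to 81.8 CPM), and the cruciferin gene CRU2 (102 to 142 CPM) were each at 0 in both pCBF3LUC libraries. Against a floor of 3 counts over the summed pCBF3LUC reads these were at least 1740-fold, 1518-fold, 647-fold, 629-fold and 985-fold higher. The orphan gene QQS was at 1.07 to 1.56 CPM against 118.9 to 119.5 (log2 −6.92 ± 0.60, 3 against 2 libraries, edgeR adjusted p = 2.52e-05), and AT3G09465 (−4.64 ± 0.71), AT5G02160 (−3.92 ± 0.76), TPX2 (−3.21 ± 0.48) and AT4G25780 (−3.18 ± 0.77) were also lower. ICE1 itself was at 58.4 to 71.2 CPM against 13.04 to 23.3 (1.55 ± 0.31, adjusted p = 0.0117), and a missense allele would not lower its count. COR genes P5CS1 (2.26 ± 0.48), COR414-TM1 (3.73 ± 0.83) and ADS2 (1.78 ± 0.40) were higher, 3 of 17, and RAB18 (4.18 ± 0.62) was the 1 of 10 abscisic acid genes to pass. With 1 surrogate variable 2 of these 10, 1 jasmonate gene and 1 immunity gene were higher, and 1 of 12 photosynthesis genes was lower (8 over the list alone). CBF3 (−1.84 ± 1.78, adjusted p = 0.638), CBF1 (−1.78 ± 1.99) and CBF2 (−1.29 ± 2.59) did not pass, and CBF1 (0.813) and CBF2 (1.212) turned sign with 1 surrogate variable. That variable, which follows the spread among 22 °C libraries, was −0.382 in the only pCBF3LUC library at 22 °C and 0.314 and −0.259 in those of ice1-1, so this spread was not balanced between the lines. In all 681 genes were higher and 133 lower. The count was 217 and 287 without the pCBF3LUC libraries at 22 and 4 °C, 483 without the 4 °C ice1-1 library, 1573 with DESeq2 and 4065 with voom. The share of higher genes depended on the fit, with 2185 higher and 1880 lower by voom, 1098 and 475 by DESeq2, 1193 and 497 with 1 surrogate variable, 204 and 13 without the 22 °C pCBF3LUC library, and 807 and 311 without CYHr1 library 1 at 22 °C.

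**Figure D3:**
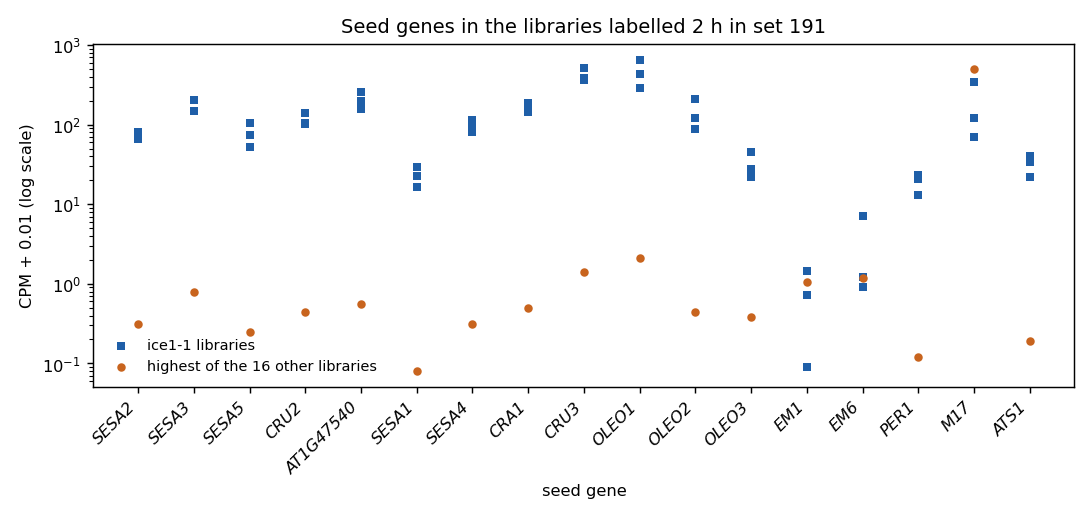
CPM (log scale, 0.01 added) of seed genes in each of the 3 ice1-1 libraries, beside the highest value among the 16 other libraries labelled 2 h in set 191. SESA3 is at 146 to 203 CPM in ice1-1 against at most 0.79 elsewhere, while M17 reaches 498 CPM outside ice1-1.

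Whether the cold response itself depended on genotype could not be settled at this depth of replication. In each of the 4 interaction tests edgeR called 0 genes, with 137 (camta123), 177 (CYHr1), 71 (los1-1) and 92 (ice1-1) at an unadjusted p under 0.05. DESeq2 called 1, 1, 1 and 0. Simulated differences of a log2 of 4 were recovered at 0%, so these counts do not show that the responses were alike. The interaction for CBF3 was −5.34 ± 4.85 in camta123, −2.62 ± 4.72 in CYHr1, 0.68 ± 3.84 in los1-1 and 1.79 ± 4.36 in ice1-1. That for CBF1 was −8.02 ± 8.05, −6.88 ± 8.19, −0.27 ± 4.46 and 1.87 ± 4.73 and for CBF2 −7.16 ± 7.61, −5.65 ± 7.33, 1.38 ± 6.09 and 1.07 ± 6.51, in the same order. No targeted gene passed in any of the 4.

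The FLAG ChIP libraries comprised 17 of CAMTA lines, 6 of FLAG-ICE1 and 1 of CBF2-FLAG, all labelled 22 °C, with 15254 to 52721 peaks each (median 22340). Where CAMTA and ICE1 lines differed in binding was asked over 85786 merged regions. None passed Fisher's exact test after adjustment, and 1721 had an unadjusted p under 0.05. The peak names inside the 23 lists read 22C DMSO (8 lists), 4C DMSO (8) or CHX (7), unlike the labels. If these words name treatments, the test pooled them within each line type. The regions on chromosome 1 from 4503115 to 4504169 and on chromosome 5 from 6723528 to 6724182 (TAIR10) had a peak in 17 of 17 CAMTA-line libraries and 0 of 6 FLAG-ICE1 libraries. The region on chromosome 5 from 16469384 to 16469783 had one in 0 of 17 and 6 of 6. Their exact p of 9.91e-06 is the smallest this design can give and was 0.283 after adjustment, so no region could pass by that test unless many reached it. A peak stood in all 23 libraries at 2142 regions. Of these the 4 at a median fold percentile of 100.0 over the CAMTA-line libraries lay on chromosome 2 from 13660677 to 13661359, chromosome 1 from 2188059 to 2188451, chromosome 5 from 8589409 to 8589878 and chromosome 3 from 10073560 to 10073939. With no untagged control used here, such regions cannot be assigned to the tagged proteins.

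**Figure D4:**
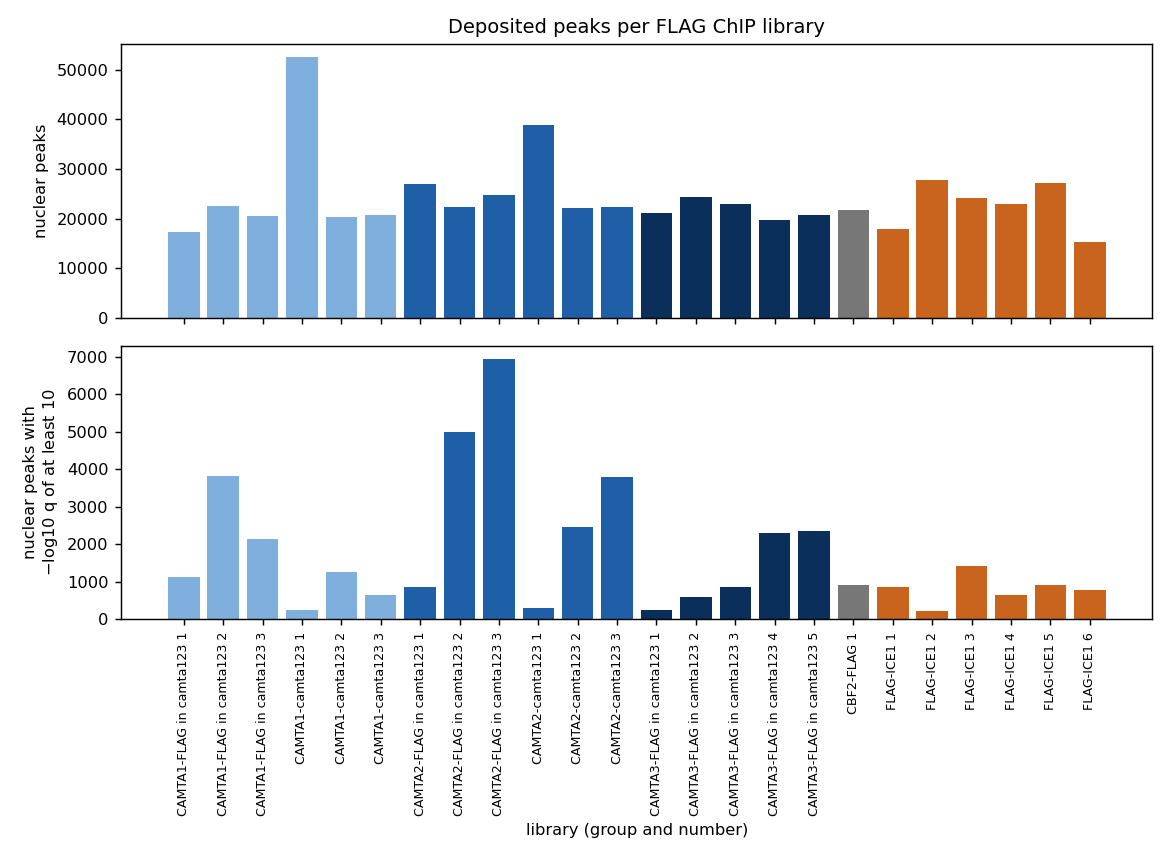
Number of nuclear peaks (top) and of those with a −log10 q of at least 10 (bottom) in each of the 24 FLAG ChIP libraries, with bars from 0 and colour for the tagged protein. CAMTA1-camta123 library 1 has 52617 nuclear peaks, of which 250 reach that q, and library 3 of CAMTA2-FLAG in camta123 has 24778, of which 6956 do.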

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

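The tests of a shared factor, of auxin genes and of CYHr1 in same-labelled libraries, and that of overlap by tagged protein, were chosen only after the result was seen. A test of the difference in cold effect between late and early times in COL passed for 11 genes, PRR5 and ELF4 among them. In data outside the comparisons, the ChIP libraries held a median of 49.0 peaks on the organelle genomes, and the CBF2-FLAG library held 21724 nuclear peaks with no other library of its kind. By a size limit chosen for it, Dixon's test was run only on CAMTA3-FLAG in camta123 (5 ChIP libraries) and FLAG-ICE1 (6). No library of these stood apart in 12 such tests. The other ChIP groups and the RNA groups, the largest being COL at 22 °C and 2 h with 12 libraries, were not tested this way.

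Most libraries labelled alike at 22 °C differed strongly. Over 9434 genes, the log2 differences within 13 same-labelled pairs had a median absolute correlation of 0.741 between pairs (0.052 to 0.933). In these pairs this may reflect 1 factor that the labels do not give. The pairs leave out the COL libraries at 22 °C and 2 h, and whether 1 factor covers those was not tested. There CBF3 was 95.9 CPM in library 11 and 1.9 in library 8. The zinc finger gene ZAT10 was lower in library 11 (979.3 against 2333.7 CPM), as was IAA1 (4.4 against 102.6). Libraries 2 and 7 were high in ZAT10 (3078.3 and 3075.4 CPM) and IAA1 (94.8 and 110.4), with CBF3 at 14.1 and 17.9. The COL pairs at 0.25 and 0.5 h, which differed little, reached at most 0.344 and 0.461 with any other pair. The log2 ratio of organelle read shares followed the shared axis (absolute uncentred correlation 0.952, opposite in direction to the auxin list, exact sign-flip p = 0.000488), as a difference in RNA quality or in organelle reads predicts, yet those shares can move nuclear genes by at most 0.145 on the log2 scale. Library size (absolute value 0.59, exact sign-flip p = 0.0955) and an unequal share of root tissue cannot be told apart from it, because both values lie between their predicted bounds. Of 9 root markers 7 moved strongly one way and 0 strongly the other. SCR (0.495) and SHR (0.44) did move the other way, below the size of 0.5 that counted as strong. An unequal root share predicts that all markers move one way, and this was not met. The auxin response list moved one way along the axis in 12 of 13 pairs. The CYHr1 pair ranked 3 of 13 from the smallest, where even rank 1 could give no p under 0.077. The smaller pairs were COL at 0.25 and 0.5 h (12.2 and 9.46), while CYHr1 was at 71.54. Other pairs of set 191 were at 121.67 to 140.11, and COL at 1 h was at 77.36. Whether CYHr1 stands apart within set 191 was not tested.

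Seed storage genes were high in the 3 ice1-1 libraries. The test argued against a few genes taking most of the reads, since seed genes held at most 0.26% of them, and against library size, since 3 of 3 totals lay inside the range of the other 16 libraries. RNA from seeds or embryos stays open: 12 seed markers outside the named genes had a median log2 fold change of 9.72 against pCBF3LUC (7.84 with 3 markers at 0 there set at their bound), and 9 were called higher. EM1, EM6 and M17 were not called. Genotype and seed content fall together in these libraries, so an effect of ice1-1 on these genes may equally give this value and was not tested apart.

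ChIP libraries of the same tagged protein shared more of their 5000 strongest peaks, 44.51% on average against 39.74% between proteins (permutation p = 0.0021). This is consistent with a part of the peaks depending on the tagged protein. Libraries with the same R number in their peak names shared 42.02% against 39.65% (permutation p = 0.05785), which leaves a library batch open.

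Regrouping the libraries tested whether chance alone could give the counts of calls. In the COL time course, 1 of 100 splits within times, the real one, gave 3781 calls and the highest other gave 573. No other split run there reached the real count. In the 7 genotypes 2 of 100 splits gave as many as the real 3481, which meets the planned bound. The highest other gave 5247, more than the real split, which points to a structure of the samples. The count there therefore cannot tell cold from another grouping of these libraries. Most libraries labelled alike differed strongly, so they may not be exchangeable, which all these splits assume. In the FLAG lines 3 of 27 splits gave as many as the real 153, and the highest other gave 4961, so chance is not excluded and a structure of the samples is seen again. For late against early times (real 11, highest other 0) and for los1-1 against C24 (real 5, highest other 0), 1 of 10 splits each, there are too few splits for a share under 0.05. For ChIP regions the real count was 0, which any split must reach (100 of 100 did, highest other 0), so nothing follows about chance.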

How the results depend on the processing

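Only the fits with 1 surrogate variable, without seed genes, on ChIP regions with peaks in at least 2 libraries, without CAMTA1-camta123 library 1 and with the R number as a block were chosen after seeing the data. No paired analysis was possible for the RNA libraries because the labels give them no replicate numbers. Peak names in 23 ChIP lists carry an R number of 1 or 2, and with it as a replicate block 0 regions passed an exact test (1891 at an unadjusted p under 0.05, smallest adjusted p 0.473). The CAMTA motif search and the test of cold-responsive genes near peaks were not run, for want of a reference genome of the build used here. Groups of 1 to 3 libraries at 4 °C limit every comparison, and where a library left out leaves 1 in a group, that one is assumed to vary like the others. No cause below was tested, except that fits with fewer libraries have fewer degrees of freedom.

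The same-sign share of 99.1% in the 7 genotypes was 98.99% with RLE factors in both fits and 98.93% with 1 surrogate variable. Within the main result it was 98.8% for genes called up and 99.4% for genes called down. The COL count of 3781 was 3773 with RLE factors, 3090 without a filter, 5616 with DESeq2, 2544 with 1 surrogate variable, 3775 with summed counts (2599 of them called in both fits, 1400 up and 2375 down against 1925 and 1856) and 5496 with the COL libraries of set 191. It was 7612 with voom and 38 without the 2 h time point. Late against early gave 11 calls, and 2556 with voom, 530 with DESeq2 and 374 with 1 surrogate variable. The 7 genotypes gave 3481, and 8369, 5544 and 7404 by the same alternatives. The FLAG lines gave 153, and 3252, 2579 and 5052. For camta123 against COL DESeq2 gave 19, 1 surrogate variable 11 and the mean of 6 other genotypes 312 (243 higher and 69 lower), and for CYHr1 these gave 19, 2 and 339 (271 and 68). For los1-1 against C24 no filter gave 2, voom 207, DESeq2 111, 1 surrogate variable 60 and the other genotypes 2158. For ice1-1 against pCBF3LUC voom gave 4065, DESeq2 1573, 1 surrogate variable 1690, the other genotypes 2572 and leaving out seed genes 791. DESeq2 gave 1 call in each of the camta123, CYHr1 and los1-1 interactions. Of the gene list tests in both cold comparisons, 11 passed camera, 1 with an estimated correlation and 6 with fry. The ChIP count was 0 in every setting run. With 1 surrogate variable 1306 of the 1925 rises and 887 of the 1856 falls in COL were called again, and 1568 of 1568 rises and 1910 of 1913 falls in the 7 genotypes.

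Leaving out 1 library at a time gave 1537 to 5373 calls for cold in COL, 0 to 268 late against early, 1447 to 4323 in the 7 genotypes and 0 to 68 in the FLAG lines. It gave 1 to 4 for camta123, 0 to 1 for CYHr1, 0 to 3 for los1-1 and 217 to 1118 for ice1-1. The interactions gave 0 to 0 without each of 17 (los1-1) or 16 libraries, since the others are needed to estimate them. ChIP regions gave 0 to 0 in the 7 fits run, without each of 6 FLAG-ICE1 libraries and without CAMTA1-camta123 library 1, while the other CAMTA-line libraries were not left out. Called named genes kept their sign throughout, with 763 values still past the threshold and 105 not in other settings, and 2217 and 697 with a library left out.

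Targeted genes and CBF1 to CBF3 that did not pass gave 605 values in other settings, of which 511 kept sign and call, 32 came to pass and 62 turned sign. Of 1884 values with a library left out these were 1794, 8 and 82. For cold in COL those that passed were CBF1 (voom 4.007, DESeq2 2.334, 1 surrogate variable 4.574), CBF2 (voom 2.36, 1 surrogate variable 3.373) and SCRM2 (voom 0.572, DESeq2 0.604, summed counts 0.47, set 191 added 0.647, and 0.598 to 0.744 in 6 left-out fits). Late against early it was ICE1 (0.95, 1.081 and 1.041 with voom, DESeq2 and 1 surrogate variable, and 1.347 without COL library 2 at 4 °C and 2 h). In the 7 genotypes voom and 1 surrogate variable gave CBF1 3.204 and 5.375, CAMTA3 −1.413 and −0.885 and LOS1 0.38 and 0.252, and the latter gave CBF2 4.505. For camta123 1 surrogate variable gave CAMTA2 −1.541. For ice1-1 SCRM2 passed with voom (1.17), DESeq2 (1.39), the other genotypes (1.451) and without CYHr1 library 1 at 22 °C (1.392). In the FLAG lines voom, DESeq2 and 1 surrogate variable gave SCRM2 0.642, 0.683 and 0.625 and ICE1 0.604, 0.629 and 0.576, while CBF3 passed with voom (5.217) and 1 surrogate variable (5.42) and CBF2 with the latter (4.482). For cold in COL the turned log2 values were, with voom ICE1 −0.031. For late against early times the turned log2 values were, with no filter CBF3 0.005, with voom CBF3 1.496, with 1 surrogate variable CBF2 0.763 and CBF3 0.958. For camta123 against COL the turned log2 values were, with voom ICE1 0.081, with 1 surrogate variable CBF3 −0.008, CBF2 −0.575 and CAMTA3 −0.075, with the mean of all 6 other genotypes CBF2 −0.581. For CYHr1 against COL the turned log2 values were, with voom CBF1 0.249, with 1 surrogate variable CBF2 −0.433, LOS1 0.006 and CAMTA2 −0.182, with the mean of all 6 other genotypes CBF2 −1.248, CAMTA3 −0.205 and ICE1 −0.187. For los1-1 against C24 the turned log2 values were, with voom CBF2 0.355 and CBF3 0.202, with 1 surrogate variable CBF2 0.624, CBF3 0.452 and CAMTA3 0.069, with the mean of all 6 other genotypes CBF2 0.543, CBF3 1.201, CAMTA2 0.191, SCRM2 −0.198 and CAMTA1 0.376. For ice1-1 against pCBF3LUC the turned log2 values were, with 1 surrogate variable CBF1 0.813, CBF2 1.212, CAMTA2 0.13 and CAMTA3 0.44, with the mean of all 6 other genotypes CBF1 0.147, CAMTA2 0.159 and CAMTA3 0.158. For the los1-1 interaction the turned log2 values were, with voom CBF3 −0.152, CBF1 1.045 and CAMTA3 0.133, with 1 surrogate variable CBF3 −0.01, with the mean of all 6 other genotypes CBF2 −1.759, CBF3 −0.628 and CAMTA1 −0.16. For the camta123 interaction the turned log2 values were, with 1 surrogate variable SCRM2 −0.137, with the mean of all 6 other genotypes CBF1 0.307 and SCRM2 −0.028. For the CYHr1 interaction the turned log2 values were, with 1 surrogate variable CAMTA3 0.598 and LOS1 −0.095, with the mean of all 6 other genotypes CBF1 1.638, CBF2 1.542, CBF3 0.976, CAMTA3 1.466 and LOS1 −0.295. For the ice1-1 interaction the turned log2 values were, with 1 surrogate variable CBF2 −0.497, CAMTA2 −0.244 and CAMTA3 −0.417, with the mean of all 6 other genotypes CBF1 −0.606, CBF2 −1.535, LOS1 0.026, CAMTA2 −0.365 and CAMTA3 −0.37. For cold in the FLAG lines the turned log2 values were, with voom CBF1 2.533, with 1 surrogate variable CBF1 2.478 and LOS1 −0.041.

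With a library left out, such genes also turned. In late against early times, the ranges were −0.668 to 1.078 (CBF3). In cold in 7 genotypes, the ranges were −0.011 to 0.179 (CAMTA1). In camta123 against COL, the ranges were −0.259 to 4.752 (CBF3), −2.101 to 7.25 (CBF1), −0.668 to 7.26 (CBF2), −0.589 to 2.411 (CAMTA3) and −0.169 to 0.046 (ICE1). In CYHr1 against COL, the ranges were −2.004 to 7.918 (CBF1), −1.215 to 2.777 (CBF3), −1.395 to 6.806 (CBF2), −0.019 to 2.0 (CAMTA3), −0.323 to 0.083 (LOS1), −0.088 to 0.2 (ICE1) and −0.221 to 0.295 (CAMTA2). In los1-1 against C24, the ranges were −2.668 to 4.271 (CBF1), −3.177 to 3.079 (CBF2), −1.745 to 1.568 (CBF3), −0.813 to 0.154 (CAMTA2), −0.187 to 0.371 (SCRM2), −0.275 to 0.11 (CAMTA1) and −1.171 to 0.741 (CAMTA3). In ice1-1 against pCBF3LUC, the ranges were −3.524 to 0.199 (CBF2), −0.683 to 0.015 (CAMTA2) and −0.386 to 0.129 (LOS1). In the camta123 interaction, the ranges were −6.329 to 1.057 (CBF3), −4.15 to 0.301 (CAMTA3), −0.028 to 0.184 (SCRM2) and −0.468 to 0.738 (CAMTA2). In the CYHr1 interaction, the ranges were −0.476 to 0.146 (CAMTA1), −0.136 to 1.323 (SCRM2), −0.934 to 0.261 (CAMTA3) and −0.094 to 0.433 (LOS1). In the ice1-1 interaction, the ranges were −0.05 to 0.676 (CAMTA2) and −0.485 to 2.929 (CAMTA3). In the los1-1 interaction, the ranges were −7.18 to 10.678 (CBF2), −5.466 to 4.996 (CBF3), −5.448 to 9.147 (CBF1), −0.639 to 0.323 (ICE1), −1.07 to 0.629 (CAMTA2), −0.389 to 0.657 (SCRM2), −0.271 to 0.481 (CAMTA1) and −1.87 to 2.18 (CAMTA3). In cold in the FLAG lines, the ranges were −1.563 to 0.915 (CBF1) and −0.103 to 0.198 (LOS1).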

Other observations

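No tests belong to this part, whose genes and libraries were chosen after their values were seen. ZAT10, an early cold and stress zinc finger gene, spanned 13.003 to 3078.3 CPM in the 11 COL libraries of set 190 labelled 22 °C and 2 h, and 275.6 and 503.7 CPM in both 4 °C libraries. IAA1 spanned 1.8 to 110.4 CPM in the same 11 libraries. Between same-labelled pairs at 22 °C, ZAT10 was 19.1 and 3292.5 CPM in camta123, 16.7 and 2460.1 in C24, 14.01 and 3208.9 in los1-1, 34.1 and 2377.5 in ice1-1, and 70.7 and 530.6 in CYHr1. CAB1, a light-harvesting gene, was 8380.5 and 594.0 CPM in the COL pair at 6 h. The difference along the shared axis was 9.46 in the COL pair at 0.5 h, 12.2 at 0.25 h, 77.36 at 1 h, 174.18 at 4 h and 189.15 at 6 h.

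CAMTA1 was at 1.29 to 2.46 CPM in the CAMTA2-FLAG and CAMTA3-FLAG lines, near the 1.00 to 2.06 CPM of camta123, and at 14.1 to 16.6 CPM in FLAG-ICE1. CAMTA3 differed between the 22 °C libraries of each tagged line, at 4.01 and 52.1 CPM in CAMTA2-FLAG, 61.0 and 421 in CAMTA3-FLAG and 12.6 and 83.2 in FLAG-ICE1. CBF3 at 4 °C was 107 CPM in CAMTA2-FLAG, 73.1 in CAMTA3-FLAG and 50.3 in FLAG-ICE1.

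The labels give 22 °C for all 24 ChIP libraries. The peak names inside the deposited lists carry other words, with 22C DMSO in 8 lists, 4C DMSO in 8 and 22C with CHX in 7. The CBF2-FLAG list reads 4C with no compound, so 4C stands in 9 lists in all. No library was grouped by these names. CAMTA1-camta123 library 1 had 52721 peaks, of which 2920 reached a q of 0.05, and shared as little as 6.2% of its strongest peaks with another library.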
